A study of Homo sapiens with 8 samples.

How the data were processed

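RNA was sequenced from sorted cells of the KG-1a line that carried a lentiviral hairpin, with a template-switching kit for low RNA input (SMART-Seq v4) and Illumina sequencing, per the labels. Groups and replicate numbers were taken from the sample titles, and each table column was matched to its sample through the library name in the labels. For the control group the numbers in the titles and in the library names differ, so that shCTL replicates 1, 2, 3 and 4 are library names 3, 4, 1 and 2. Nothing in the labels says whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Bowtie 0.12.9, Cufflinks 2.1.1 and HTSeq are named in the submitters' processing notes, which list both mm10 and hg38 with no role for either. The alignment settings, annotation and strand setting are not given in the sources used here, so overlapping and near-identical genes remain uncertain.

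The deposited values of 7 libraries are read as FPKM from their scale and decimals and from Cufflinks among the tools, since no header names a unit. Each library summed to between 308998 and 313691, and 12287 to 12557 of the genes listed in both tables had at least 1 FPKM. In the first deposited table the value 0.001 stands in place of 0. The deposited column of shCTL replicate 3 is treated as a score, since it holds whole numbers. Of 829 genes that lay between 0.5 and 0.9 FPKM in shCTL replicate 4 and shNYNRIN replicate 3, 762 (91.9%) were listed at 0 there. Between 10 and 30 FPKM its median difference to shCTL replicate 4 was -0.5003, the pattern of FPKM truncated to the whole number below. The first table also holds the authors' mean normalized count over its 4 libraries, the authors' log2 fold change, and the authors' p-value and q-value, and the program behind them is not given in the sources used here. The authors' marks of up and down went with an unadjusted p-value under 0.05 (1921 and 1986 genes), and the deposited q-value was 1 for 990 genes of low mean count. The read depth of single libraries is not given in the sources used here, so no counting interval is attached to a value.

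The analysis planned before the data were examined took all 8 libraries in 1 unit. Because shCTL replicate 3 was deposited as whole numbers, without the decimals of the other libraries, it was left out of the tests. This choice was made after the files had been looked at, and results with that library are given among the alternatives. Log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, for genes of at least 1 FPKM in at least 2 libraries. Fold changes are on that scale and understate the change of low genes. Tests were two-sided, with Benjamini-Hochberg adjustment over 12939 genes and a threshold of 0.05. The model over both sets had group and table as additive terms and 4 residual degrees of freedom. Effects within each set and their difference came from a model with the interaction and 3 residual degrees of freedom, in which the 1 control library of set 2 is assumed to vary like the others. The interaction was planned, and reading the effect of each set from it was added after the data were seen. Replicates of set 1 differed by 3.45 (shCTL) and 5.44 (shNYNRIN) times the counting noise that the authors' mean counts imply, so none was counted as another library deposited again. This does not tell whether they were technical repeats.

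Whether replicate numbers pair the libraries was checked by correlating deviations from the group means over 5880 genes of at least 10 FPKM, with 0.5 added to shCTL replicate 3. By the numbers in the library names, which come from the labels, shCTL and shNYNRIN libraries of the same number had an r of 0.102, 0.141, 0.153 and 0.147. The highest r of each shCTL library with an shNYNRIN library of another number was 0.180, 0.144, 0.141 and 0.162, so only library-name number 3 was closest to its own number, and 1 and 2, and 3 and 4, deviated together. Each of these pairs spans both tables, and the group means were taken over both tables. The r values therefore also carry the difference between the sets and cannot show by themselves that the numbers pair the libraries. As every pair had an r over 0.1, a block by these numbers is given beside the results it changes.

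Gene lists and cell type markers were fixed before the data were examined. They were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, in 32 lists with at least 3 measured members, a minimum that was set afterwards. Marker lists were adjusted as a family of their own. The rule for named genes, also fixed beforehand, took NYNRIN and TXNIP, the 10 largest rises and 10 largest falls among genes that passed over both sets with the same sign in each, up to 4 members of a list that passed or had 3 members past the threshold, and at most 2 of any other list. Its use within each set and for the difference between sets, with 5 genes per direction, was added after the data were seen. GATA1, PTMA, the lineage genes named for their levels and the genes named under other observations were chosen after their values were seen. Results for some single genes are not reported here. Alternatives covered normalization, pseudocount, filter, table term, replicate block, trend, library weights, thresholds, the set test, each table alone and each library left out, with others added after the data were seen. Coordinates are from GENCODE 29, and figures were drawn with matplotlib 3.10.9.

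The steps were tested on simulated data with 200 of 12939 genes changed by log2 sizes of 0.25, 0.5, 1 and 2. For the test over both sets each change was simulated alike in both sets, and no gene differed in effect between them. Recovery over both sets of effects that differ between the sets, as those of 2636 genes did here, was not simulated. Over both sets 54%, 82%, 98% and 100% of the changed genes were recovered, with 12 false calls. The shares were 24%, 72%, 94% and 98% for set 1 with 7 false calls, 22%, 66%, 94% and 100% for set 2 with 13, and 6%, 38%, 76% and 96% for the difference between sets with 8.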

Results

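To ask what loss of NYNRIN does to the transcriptome of leukaemic cells, RNA was sequenced from cells labelled KG-1a, an established human acute myeloid leukaemia line. The cells carried a lentiviral short hairpin RNA against NYNRIN (shNYNRIN) or a control hairpin (shCTL). There were 4 libraries per group, deposited as 2 tables with 2 libraries of each group in each. The tables are called set 1 (replicates 1 and 2 of each group) and set 2 (replicates 3 and 4 of each group). Values are read as FPKM. ShCTL replicate 3 was deposited as whole numbers and was left out of the tests, so 3 shCTL and 4 shNYNRIN libraries entered them, and set 2 rested on 1 control library. The read depth of single libraries is not given in the sources used here. The mean normalized counts in the authors' deposited table summed to 38530000 per library of set 1. The low values of set 2 placed shNYNRIN replicates 3 and 4 at 1.34 and 1.30 times the depth of shCTL replicate 4.

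NYNRIN, the target of the hairpin, was lower in each shNYNRIN library than in each shCTL library. The gene (ENSG00000205978) is protein coding and lies on the plus strand of chromosome 14 from 24398786 to 24419288 in the GRCh38 annotation of GENCODE 29. In set 1 it fell from 12.3 ± 0.183 FPKM to 7.14 ± 0.226 FPKM (SD, n = 2 each), a log2 fold change of -0.71 (SE 0.052, limma adjusted p = 0.000984). In set 2 it fell from 10.4 FPKM in shCTL replicate 4 to 2.84 ± 0.00856 FPKM (SD, n = 2), a log2 fold change of -1.57 (SE 0.064, limma adjusted p = 0.000119), with shCTL replicate 3 listed at 10. The fall was deeper in set 2, with a difference of -0.85 between the log2 fold changes (limma adjusted p = 0.00132). A single effect fitted to both sets gave a log2 fold change of -1.05 (SE 0.16) that did not pass the threshold (limma adjusted p = 0.0612, 0.000303 to 0.423 over 23 alternatives). Without shCTL replicate 4, which leaves set 1 alone to estimate it, it was -0.71 and passed (limma adjusted p = 0.00116).

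TXNIP, which encodes a binding partner and inhibitor of thioredoxin, is named in the title of the series. RNA levels, given here, do not measure the TXNIP protein or its stability. TXNIP was higher in each shNYNRIN library than in each shCTL library. The gene (ENSG00000265972) is protein coding and lies on the minus strand of chromosome 1 from 145992435 to 145996600 in the same annotation. In set 1 TXNIP rose from 79.2 ± 1.96 FPKM to 139.6 ± 1.36 FPKM (SD, n = 2 each), a log2 fold change of 0.81 (SE 0.029, limma adjusted p = 0.000191). The authors' deposited table gives a log2 fold change of 0.79 for TXNIP in the same libraries. In set 2 TXNIP stood at 95.4 FPKM in shCTL replicate 4 and at 102 ± 1.24 FPKM (SD, n = 2) with shNYNRIN, a log2 fold change of 0.10 (SE 0.036) that did not pass the threshold (limma adjusted p = 0.0977, 0.0399 to 0.295 over 18 alternatives). With shCTL replicate 3 included as deposited, at 97, the value was 0.088 and passed (limma adjusted p = 0.0474). The TXNIP effects of the sets differed by -0.71 (limma adjusted p = 0.000463). A single effect fitted to both sets was 0.53 (SE 0.13, limma adjusted p = 0.118) and, without shCTL replicate 4, 0.81 (limma adjusted p = 0.000189, the lowest of 27 alternatives, of which the highest was 0.445). With the library-name number as a block, the TXNIP log2 fold change was 0.43 (limma adjusted p = 0.183). With that block, shCTL replicate 3 plus 0.5 and genes of at least 10 FPKM, it was 0.45 and passed (limma adjusted p = 0.0281).

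**Figure D1:**
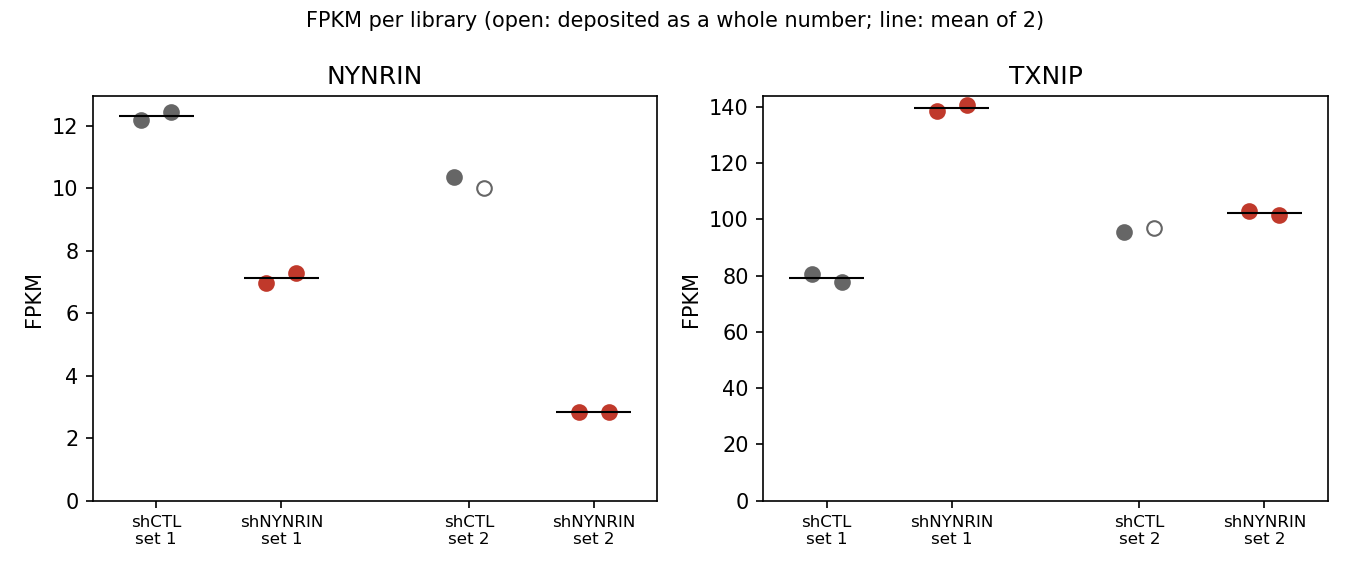
FPKM of NYNRIN (left) and TXNIP (right) in each library, by group and set; each point is 1 library, lines are means of 2 libraries, and the open point is the control library deposited as whole numbers. NYNRIN is lower in the shNYNRIN libraries of both sets, while TXNIP goes from a mean of 79.2 to 139.6 FPKM in set 1 and from 95.4 to a mean of 102 FPKM in set 2.

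A first comparison fitted a single effect of shNYNRIN to both sets. SCAMP5, a secretory carrier membrane protein, rose from 7.33 ± 0.103 to 11.3 ± 0.926 FPKM in set 1 and from 4.54 to 8.84 ± 0.638 FPKM in set 2 (SD, n = 2 where given), a log2 fold change of 0.67 over both sets. ARL2, a small GTPase that acts in tubulin folding, rose by 0.61 on the log2 scale, and the lymphocyte activation marker CD69 rose from 78.0 ± 0.242 to 104 ± 4.91 FPKM in set 1 and from 78.5 to 110.4 ± 6.26 FPKM in set 2 (0.44). HOXB9, a homeobox transcription factor, fell from 41.6 ± 1.52 to 25.5 ± 0.439 FPKM in set 1 and from 34.4 to 24.4 ± 0.00877 FPKM in set 2 (-0.60). RBM3, a cold-inducible RNA-binding protein, fell by 0.40 on the log2 scale, and ACSL4, which activates polyunsaturated fatty acids, fell by 0.43.

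In total 41 of 12939 genes passed an adjusted p of 0.05 in the limma model with a table term, 25 higher and 16 lower in shNYNRIN, with log2 fold changes between 0.27 and 0.67 in size and a lowest adjusted p of 0.03999. All 41 had the same sign in both sets, and 1 of them, prothymosin alpha (PTMA), also differed in effect between the sets, at -0.41 and -0.24 (limma adjusted p = 0.0207). That PTMA difference was lost without shCTL replicate 1 or shNYNRIN replicate 3 or 4 (limma adjusted p up to 0.0874). A model with a single effect for both sets favours genes that change alike, since a difference between the sets adds to its residual spread. The shared sign of the 41 genes is therefore no separate evidence that the sets agree. The other genes among the 10 largest rises were HSD17B14 (log2 fold change 0.62), the chemokine receptor CCR4 (0.56), LINC01426 (0.48), lysozyme (LYZ, 0.47), AIG1 (0.45), the receptor phosphatase PTPRF (0.44) and the transglutaminase TGM2 (0.43). The other genes among the 10 largest falls were ENSG00000288066 (log2 fold change -0.54), TUBAL3 (-0.53), the phosphatase DUSP2 (-0.52), PCAT14 (-0.47, with shNYNRIN replicate 2 apart from the other shNYNRIN libraries at 20.8 FPKM), the splicing factor SNRNP27 (-0.44), TERLR1 (-0.37) and the transcription factor CEBPG (-0.36). With limma, 0 genes passed when any of shCTL replicates 1 and 2 or shNYNRIN replicates 1, 2, 3 and 4 was left out, although 1807 to 2080 genes then had an unadjusted p under 0.05 against 2423 with all 7 libraries. Without shCTL replicate 4, 2065 genes passed, and with the library-name number as a block in place of the table, 0 did (2188 at an unadjusted p under 0.05). Quantile normalization gave 4 higher and 4 lower genes, and upper-quartile scaling 10 higher and 19 lower. When the effect was free to differ between the sets and was averaged over them, 2304 genes passed, among them all 41 of these.

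The replicative helicase subunits MCM5 and MCM3 had log2 fold changes of -0.39 and -0.33 over both sets. They belong to DNA replication and S phase, 1 of 4 among 32 gene lists that passed camera over both sets, with a median log2 fold change of -0.13 over 33 measured genes. For replication genes the camera adjusted p was 1.05e-09 (adjusted p = 0.693 with an estimated correlation). The 68 cytosolic ribosomal protein genes had a median of -0.074, with RPL14 at -0.23. For ribosomal protein genes the camera adjusted p was 2.65e-15 (adjusted p = 0.693 with an estimated correlation). The 27 mitosis genes had a median of 0.14, with survivin (BIRC5), a chromosomal passenger protein, at 0.32. For mitosis genes the camera adjusted p was 0.000261 (adjusted p = 0.766 with an estimated correlation). The 13 core histone genes had a median of 0.41, with H2BC12 at 0.74. For core histone genes the camera adjusted p was 0.00566 (adjusted p = 0.707 with an estimated correlation). By limma 0 members of these 4 lists passed over all genes, while 13 replication, 26 ribosomal protein, 13 mitosis and 7 histone genes had an unadjusted p under 0.05. Adjusted over the list alone, 6 replication and 11 ribosomal protein genes were lower and 8 mitosis and 6 histone genes higher. Within sets 1 and 2 the medians were -0.032 and -0.31 for replication, -0.11 and -0.043 for ribosomal protein, 0.23 and -0.019 for mitosis and 0.14 and 0.80 for histone genes. Those of replication and histone genes were larger in size in set 2, with its 1 control library. Without shCTL replicate 4 the replication and histone lists did not pass (camera adjusted p = 0.0983 and 0.277, with ranges of 5.88e-16 to 0.0983 over 27 alternatives and 0.000107 to 0.352 over 23 alternatives). In set 2 alone the mitosis list had a mean log2 fold change of -0.013, and fry, which does not compare a list with other genes, passed 0 lists over both sets (7 at an unadjusted p under 0.05).

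In set 1, where each group had 2 libraries, CHAC1, which degrades glutathione, fell from 9.77 ± 1.25 to 3.34 ± 0.246 FPKM (SD, n = 2 each), a log2 fold change of -1.31. The serine synthesis enzymes PSAT1 and PHGDH fell by 0.78 and 0.67 on the log2 scale, and the transcription factor ATF4, which induces them, fell by 0.36. EGR1, a growth-induced transcription factor, fell from 215 ± 9.16 to 124 ± 3.33 FPKM (-0.79), and the AP-1 subunits FOSB and FOS fell by 0.60 and 0.56. Cyclin B1 (CCNB1), which drives entry into mitosis, rose from 60.8 ± 0.130 to 87.0 ± 3.49 FPKM (0.51), and CDC20, which activates the anaphase-promoting complex, rose by 0.52.

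By limma 2062 of 12939 genes changed in set 1, 1207 higher and 855 lower. By library-name number, set 1 compares shCTL 3 and 4 with shNYNRIN 1 and 2, and set 2 the reverse, so each gene and list effect within a set also carries any difference between these numbers. The authors' deposited table holds 2607 genes with a q-value under 0.05, of which 1228 were higher, and 1772 of the 2062 genes were among them with the same sign. With upper-quartile scaling 823 genes were higher and 1148 lower. The 5 largest rises were in MIR6813, CYCSP10, RNU6-1153P, RNU6-30P and the histone gene H2AC13, with log2 fold changes of 1.40, 1.26, 1.18, 1.11 and 1.09. Besides CHAC1, the largest falls were in ENSG00000284651, MIR6739, RNU7-20P and MIR548AN, with log2 fold changes of -1.61, -1.36, -1.33 and -1.17. Small RNAs, histone genes and pseudogenes share sequence with near-identical copies, so these values are uncertain, and MIR6813 had 1.15 FPKM and the stand-in value 0.001 in the shCTL libraries. The calls of MIR6813, RNU6-1153P, RNU6-30P, H2AC13, ENSG00000284651, RNU7-20P and MIR548AN were each lost without 1 or more of shCTL replicates 1 and 2 and shNYNRIN replicates 1, 2, 3 and 4, with a limma adjusted p of up to 0.160. The authors' unadjusted p-value lay between 0.0768 and 0.210 for MIR6813, RNU6-1153P, RNU6-30P, ENSG00000284651, MIR6739, RNU7-20P and MIR548AN. It was under 0.05 for CYCSP10, H2AC13 and CHAC1. By the authors' q-value H2AC13 and CHAC1 passed 0.05, and CYCSP10, among the 990 genes of low mean count, did not. Without shCTL replicate 1 there were 588 genes, without shCTL replicate 2, 617, without shNYNRIN replicate 3 1232 and without shNYNRIN replicate 4 1249.

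The kinesin KIF20A and the ubiquitin-conjugating enzyme UBE2C, which act in cell division, rose in set 1 by 0.46 and 0.31 on the log2 scale. Among 27 mitosis genes 16 rose (20 adjusted over the list alone). For mitosis genes the camera adjusted p was 9.99e-11 (adjusted p = 0.201 with an estimated correlation). Of 68 ribosomal protein genes 32 fell (44 adjusted over the list alone), with RPS27 at -0.38 and RPL10 at -0.23. For ribosomal protein genes the camera adjusted p was 7.3e-16 (adjusted p = 0.282 with an estimated correlation). Of 18 immediate early genes 8 fell (1 higher and 9 lower adjusted over the list alone), with IER2 at -0.34. For immediate early genes the camera adjusted p was 1.43e-06 (adjusted p = 0.282 with an estimated correlation). In the ferroptosis and iron list 6 fell (7 adjusted over the list alone) of 15 genes, among them the iron exporter SLC40A1 (-0.30) and the cystine transporter SLC7A11 (-0.63). For the ferroptosis list the camera adjusted p was 0.00116 (adjusted p = 0.282 with an estimated correlation). The SLC7A11 call was lost without shCTL replicate 1 (limma adjusted p = 0.0656, 0.0104 to 0.0656 over 15 alternatives).

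HSPH1, a co-chaperone of the heat shock response, rose in set 1 by 0.60 on the log2 scale, while the constitutive chaperone HSPA8 fell by 0.17. Of 11 heat shock genes 6 rose and 1 fell (8 and 1 adjusted over the list alone). For heat shock genes the camera adjusted p was 0.0101 (adjusted p = 0.282 with an estimated correlation). Among 15 superoxide and peroxide scavengers 4 rose (5 adjusted over the list alone), with mitochondrial superoxide dismutase (SOD2) at 0.47 and the glutathione peroxidase GPX1 at 0.26. For scavengers the camera adjusted p was 0.0101 (adjusted p = 0.282 with an estimated correlation). In the list of mitochondrial permeability and calcium handling 3 rose (7 adjusted over the list alone) of 15 genes, with the outer membrane channel VDAC1 at 0.17 and cyclophilin D (PPIF) at 0.18. For the mitochondrial permeability list the camera adjusted p was 0.0274 (adjusted p = 0.404 with an estimated correlation). Of 21 stem and progenitor genes 7 fell (8 adjusted over the list alone), with the transcription factors MYB and GATA2 at -0.32 and -0.27. For stem and progenitor genes the camera adjusted p was 0.0420 (adjusted p = 0.298 with an estimated correlation). Without shCTL replicate 1 the calls of VDAC1 and PPIF were lost (limma adjusted p = 0.0563 and 0.0546, with ranges of 0.00107 to 0.0686 over 18 alternatives and 0.000874 to 0.0647 over 18 alternatives). The mitochondrial list did not pass without shCTL replicate 1 or shNYNRIN replicate 1 (camera adjusted p = 0.104 and 0.0597, 0.00619 to 0.104 over 18 alternatives), and the stem and progenitor list did not pass without shCTL replicate 1, shNYNRIN replicate 1, shNYNRIN replicate 3 or shNYNRIN replicate 4 (camera adjusted p = 0.0686, 0.0597, 0.0606 and 0.0607, 0.0115 to 0.160 over 18 alternatives). With genes of at least 10 FPKM alone, the heat shock, scavenger and ferroptosis lists did not pass (camera adjusted p = 0.0706, 0.1001 and 0.0706, with lowest values over 18 alternatives of 0.003001, 0.00211 and 0.000504). In all 8 of 32 lists passed camera in set 1, 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 17 with fry.

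In set 2 thymidylate synthase (TYMS), which makes a precursor of DNA, fell from 45.9 FPKM in shCTL replicate 4 to 15.2 ± 1.32 FPKM (SD, n = 2), a log2 fold change of -1.54, and the helicase subunit MCM6 fell from 99.5 to 63.8 ± 0.699 FPKM (-0.63). The chaperones HSPA8 and HSPA5 fell by 0.57 and 0.67 on the log2 scale, and beta-2 microglobulin (B2M), the light chain of MHC class I, fell by 0.42. FOS rose from 96.7 to 188 ± 0.323 FPKM (0.95), EGR1 from 200.3 to 267 ± 1.31 FPKM (0.41), and the histone gene H2BC12 from 38.8 to 83.5 ± 1.85 FPKM (1.09). The creatine transporter SLC6A8 fell from 13.7 to 2.98 ± 0.351 FPKM (-1.88), and HPGD, which inactivates prostaglandins, rose from 5.47 to 19.1 ± 1.03 FPKM (1.64).

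By limma 2631 of 12939 genes changed in set 2, 1504 higher and 1127 lower, with the lone control library assumed to vary like the others and the library-name numbers again differing between the groups. The other genes among the 5 largest rises were ENSG00000279602 (log2 fold change 2.06), the pseudogene SOD1P3 (1.54), ENSG00000242156 and a Y RNA, Y_RNA|ENSG00000199875. ENSG00000242156 and the Y RNA were listed at 0 in shCTL replicate 4, and at 2.90 and 1.72 FPKM and 2.25 and 1.60 FPKM in shNYNRIN replicates 3 and 4. The other genes among the 5 largest falls were the small RNA BCYRN1 (-2.0), the complex I subunit NDUFA1 (-1.69) and NYNRIN itself. Pseudogenes and small RNAs share sequence with near-identical copies, so their values are uncertain. Without shNYNRIN replicate 3 there were 1195 genes and without shNYNRIN replicate 4 there were 1169.

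Among 33 measured replication genes 23 fell (1 higher and 27 lower adjusted over the list alone) in set 2. For replication genes the camera adjusted p was 5.69e-17 (adjusted p = 0.112 with an estimated correlation). Of 11 heat shock genes 8 fell (9 adjusted over the list alone). For heat shock genes the camera adjusted p was 7.09e-09 (adjusted p = 0.116 with an estimated correlation). Of 21 glycolysis genes 3 rose and 12 fell (3 and 13 adjusted over the list alone), with the enzymes ENO1 at -0.37 and TPI1 at -0.44. For glycolysis genes the camera adjusted p was 0.000109 (adjusted p = 0.3003 with an estimated correlation). In the list of MYC and ribosome biogenesis 2 rose and 10 fell (2 and 12 adjusted over the list alone) of 25 genes, with the polyamine enzymes SRM at -0.44 and ODC1 at -0.48. For the MYC list the camera adjusted p was 0.000102 (adjusted p = 0.145 with an estimated correlation). Among 69 nuclear genes of oxidative phosphorylation 1 rose and 14 fell (1 and 14 adjusted over the list alone). For oxidative phosphorylation the camera adjusted p was 0.000791 (adjusted p = 0.256 with an estimated correlation). Camera passed 16 of 32 lists in set 2, 6 towards higher and 10 towards lower values, while 0 passed with an estimated correlation (9 at an unadjusted p under 0.05) and 21 with fry.

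RELB, a subunit of NF-kB, fell in set 2 by 0.86 on the log2 scale, and 1 rose and 8 fell (1 and 8 adjusted over the list alone) among the 17 NF-kB and inflammatory genes. For NF-kB genes the camera adjusted p was 0.000754 (adjusted p = 0.145 with an estimated correlation). Of 8 genes of MHC class I 4 fell (4 adjusted over the list alone). For MHC class I the camera adjusted p was 0.00278 (adjusted p = 0.206 with an estimated correlation). Of 15 scavengers 5 fell (7 adjusted over the list alone), with catalase (CAT), which breaks down hydrogen peroxide, at -0.45. For scavengers the camera adjusted p was 0.000574 (adjusted p = 0.145 with an estimated correlation). Of 15 hypoxia genes 1 rose and 6 fell (2 and 7 adjusted over the list alone), with the mitophagy receptor BNIP3 at -1.03. For hypoxia genes the camera adjusted p was 0.0288 (adjusted p = 0.374 with an estimated correlation). Of 68 ribosomal protein genes 9 fell (8 adjusted over the list alone). For ribosomal protein genes the camera adjusted p was 0.00113 (adjusted p = 0.414 with an estimated correlation). With quantile normalization the ribosomal protein list did not pass (camera adjusted p = 0.950, 3.92e-05 to 0.950 over 18 alternatives). With genes of at least 10 FPKM alone the NF-kB and hypoxia lists did not pass (camera adjusted p = 0.101 and 0.0664, with ranges of 0.000494 to 0.102 over 18 alternatives and 0.00363 to 0.0664 over 18 alternatives).

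MECOM, a transcription factor of blood stem cells, rose in set 2 by 0.83 on the log2 scale, and 10 rose and 2 fell (12 and 2 adjusted over the list alone) among 21 stem and progenitor genes. For stem and progenitor genes the camera adjusted p was 0.000498 (adjusted p = 0.145 with an estimated correlation). Of 18 immediate early genes 12 rose and 2 fell (13 and 2 adjusted over the list alone). For immediate early genes the camera adjusted p was 2.17e-06 (adjusted p = 0.145 with an estimated correlation). Of 8 myeloid differentiation genes 5 rose (5 adjusted over the list alone), with lactoferrin (LTF) at 0.96 and the surface receptor CD33 at 0.38. For myeloid genes the camera adjusted p was 0.00118 (adjusted p = 0.145 with an estimated correlation). Of 13 core histone genes 9 rose (9 adjusted over the list alone). For core histone genes the camera adjusted p was 0.000102 (adjusted p = 0.145 with an estimated correlation). Of 21 autophagy and lysosome genes 6 rose (7 higher and 1 lower adjusted over the list alone), with cathepsin B (CTSB) at 0.51. For autophagy genes the camera adjusted p was 0.0232 (adjusted p = 0.219 with an estimated correlation). Of 25 NRF2 targets 7 rose and 1 fell (7 and 1 adjusted over the list alone), with the aldo-keto reductase AKR1C3 at 0.94. For NRF2 targets the camera adjusted p was 0.0325 (adjusted p = 0.219 with an estimated correlation). With genes of at least 10 FPKM alone the autophagy and NRF2 lists did not pass (camera adjusted p = 0.320 and 0.181, with ranges of 0.0161 to 0.320 over 18 alternatives and 0.0149 to 0.184 over 18 alternatives).

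Lists that passed camera in only 1 set were read in the other, where they did not pass. In set 2, of the mitosis genes 2 rose and 4 fell (3 and 4 adjusted over the list alone), in the ferroptosis and iron list 6 rose and 4 fell (7 and 4 adjusted over the list alone), and in the mitochondrial permeability list 2 rose and 3 fell (2 and 3 adjusted over the list alone), with a camera adjusted p of 0.447, 0.334 and 0.884. In set 1, of the replication genes 4 rose and 7 fell (8 and 11 adjusted over the list alone), of the glycolysis genes 4 rose (4 adjusted over the list alone), in the MYC list 4 rose (4 adjusted over the list alone), of the NF-kB genes 5 rose (5 higher and 1 lower adjusted over the list alone) and in oxidative phosphorylation 3 rose and 2 fell (2 and 1 adjusted over the list alone). Their camera adjusted p in set 1 was 0.0980, 0.0650, 0.231, 0.159 and 0.765. Also in set 1, of the MHC class I genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), of the hypoxia genes 2 rose and 1 fell (5 and 3 adjusted over the list alone), of the myeloid genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), of the core histone genes 3 rose (5 higher and 1 lower adjusted over the list alone), of the autophagy genes 4 rose and 1 fell (5 and 1 adjusted over the list alone) and of the NRF2 targets 2 rose and 4 fell (3 and 4 adjusted over the list alone). Their camera adjusted p was 0.737, 0.706, 0.409, 0.285, 0.789 and 0.471.

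The title of the series names redox balance, so lists of that kind were read in both sets. Camera passed none of the lists given here, while fry, which does not compare a list with other genes, passed some. In set 1 fry passed the thioredoxin list towards higher values (fry adjusted p = 0.000149). It passed the pentose phosphate list there towards lower values (fry adjusted p = 0.0211), and not the glutathione list (fry adjusted p = 0.163). In set 2, with 1 control library, fry passed the glutathione and pentose phosphate lists towards higher values and not the thioredoxin list. ARRDC4, a paralogue of TXNIP, rose in set 1 from 12.4 ± 0.896 to 22.7 ± 1.81 FPKM (SD, n = 2 each), a log2 fold change of 0.82 (limma adjusted p = 0.00166), and stood at 0.29 in set 2 (limma adjusted p = 0.0519). With TXNIP, ARRDC4 belongs to the list of the thioredoxin and peroxiredoxin system, of which 6 rose (6 adjusted over the list alone) in set 1 and 2 rose and 1 fell (2 and 1 adjusted over the list alone) in set 2 among 20 measured genes. For the thioredoxin system the camera adjusted p was 0.0815 in set 1 and 0.884 in set 2. The rises of set 2 were those of TXN2 (0.31) and GLRX (0.45), both lost without shNYNRIN replicate 3 or 4 (limma adjusted p up to 0.0595 and 0.0787), and the fall was that of the mitochondrial peroxiredoxin PRDX3 (-0.36). Of 22 genes of glutathione synthesis and peroxidases 4 rose and 4 fell (5 and 4 adjusted over the list alone) in set 1, and 7 rose and 3 fell (7 and 4 adjusted over the list alone) in set 2, with isocitrate dehydrogenase (IDH1) at 0.83 there. For the glutathione list the camera adjusted p was 0.737 in set 1 and 0.118 in set 2. Of 7 pentose phosphate genes 1 fell (1 adjusted over the list alone) in set 1, the transketolase TKT (-0.19), and 2 rose (2 adjusted over the list alone) in set 2, with TKT at 0.21 there. For the pentose phosphate list the camera adjusted p was 0.363 in set 1 and 0.227 in set 2. The TKT calls were lost without shCTL replicate 2 in set 1 and without shNYNRIN replicate 3 or 4 in set 2 (limma adjusted p up to 0.0883 and 0.0802).

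Venetoclax, which the title also names, is an inhibitor of BCL2, and the BCL2 family was read for that reason. The anti-apoptotic MCL1 fell in set 1 from 128 ± 2.16 to 101 ± 7.29 FPKM (log2 fold change -0.33, limma adjusted p = 0.00836) and had a log2 fold change of 0.11 in set 2 (limma adjusted p = 0.245). BCL2 stood at 2.30 ± 0.0588 and 2.87 ± 0.0454 FPKM in set 1 (log2 fold change 0.23, limma adjusted p = 0.103) and fell in set 2 from 2.92 to 1.88 ± 0.0716 FPKM (log2 fold change -0.45, limma adjusted p = 0.0226). The pro-apoptotic BAK1 rose in both sets, by 0.26 (limma adjusted p = 0.0304) and 0.31 (limma adjusted p = 0.0269). Of 5 anti-apoptotic members 1 fell (1 higher and 2 lower adjusted over the list alone) in set 1 and 1 fell (1 adjusted over the list alone) in set 2. For the anti-apoptotic members the camera adjusted p was 0.480 in set 1 and 0.926 in set 2. Of 8 pro-apoptotic members 3 rose and 1 fell (3 and 1 adjusted over the list alone) in set 1 and 2 rose (2 adjusted over the list alone) in set 2. For the pro-apoptotic members the camera adjusted p was 0.543 in set 1 and 0.149 in set 2. The MCL1 call was lost without shCTL replicate 2 (limma adjusted p = 0.0540, 0.000522 to 0.0540 over 18 alternatives), and that of BCL2 in set 2 without shNYNRIN replicate 3 or 4 (limma adjusted p = 0.0760 and 0.0988, 0.0139 to 0.217 over 15 alternatives). The BAK1 call of set 1 was lost without shCTL replicate 1 or 2 or shNYNRIN replicate 1 or 2 and that of set 2 without shNYNRIN replicate 3, with a limma adjusted p of up to 0.137 and 0.110.

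Caspase 6 (CASP6) rose by 0.41 in set 1, and the apoptosis inhibitor BIRC3 fell by 0.54 in set 2. Unlike camera, fry passed some lists of this part in set 1. These were caspases, tricarboxylic acid cycle and cholesterol synthesis towards higher values (fry adjusted p = 0.00596, 0.00272 and 0.0398). The stress response passed towards lower values (fry adjusted p = 0.00553). Of 20 caspases and death receptors 6 rose (9 higher and 2 lower adjusted over the list alone) in set 1 and 3 fell (3 adjusted over the list alone) in set 2. For the caspase list the camera adjusted p was 0.0650 in set 1 and 0.949 in set 2. Of 19 p53 targets 2 rose and 4 fell (3 and 4 adjusted over the list alone) in set 1 and 3 rose and 3 fell (3 and 3 adjusted over the list alone) in set 2. For p53 targets the camera adjusted p was 0.684 in set 1 and 0.926 in set 2. Of 23 genes of the tricarboxylic acid cycle 4 rose and 1 fell (4 and 1 adjusted over the list alone) in set 1 and 1 rose and 3 fell (1 and 3 adjusted over the list alone) in set 2, with the dehydrogenase subunit DLD at -0.43 there. For the tricarboxylic acid cycle the camera adjusted p was 0.0529 in set 1 and 0.194 in set 2. Of 26 genes of the integrated stress and unfolded protein response 4 rose and 6 fell (5 and 6 adjusted over the list alone) in set 1 and 8 rose and 5 fell (8 and 6 adjusted over the list alone) in set 2. For the stress response list the camera adjusted p was 0.221 in set 1 and 0.926 in set 2. Of 13 leukaemia stem cell score genes other than NYNRIN 3 fell (3 adjusted over the list alone) in set 1 and 5 rose and 3 fell (6 and 3 adjusted over the list alone) in set 2, with SMIM24 at -0.83 there. For the stem cell score the camera adjusted p was 0.134 in set 1 and 0.527 in set 2. Of 4 cyclin-dependent kinase inhibitors 1 rose and 1 fell (1 and 2 adjusted over the list alone) in set 1 and 1 rose and 2 fell (1 and 2 adjusted over the list alone) in set 2, with CDKN2D at -0.81 there. For the kinase inhibitors the camera adjusted p was 0.363 in set 1 and 0.227 in set 2. Of 24 interferon-stimulated genes 1 rose (by limma 0 adjusted over the list alone, 10 at an unadjusted p under 0.05) in set 1 and 2 rose and 4 fell (2 and 5 adjusted over the list alone) in set 2. For interferon-stimulated genes the camera adjusted p was 0.556 in set 1 and 0.358 in set 2. Of 19 genes of cholesterol synthesis 3 rose (2 adjusted over the list alone) in set 1 and 2 rose and 3 fell (2 and 4 adjusted over the list alone) in set 2, with INSIG1, which holds back sterol synthesis, at -0.60 there. For cholesterol synthesis the camera adjusted p was 0.222 in set 1 and 0.194 in set 2. The 2 measured MHC class II genes, CD74 and CIITA, had log2 fold changes of 0.12 and -0.14 in set 1 and -0.017 and 0.16 in set 2 and were not tested as a list, and mitochondrially encoded transcripts were not analysed here. The median, the mean and the camera direction differed in sign for p53 targets in every comparison. They also did so for anti-apoptotic members and the integrated stress response in both sets; for NRF2 targets, cyclin-dependent kinase inhibitors, MHC class I and erythroid and B cell markers in set 1; for the thioredoxin system, caspases, mitochondrial permeability, interferon-stimulated genes and B cell markers in set 2; for scavengers, pentose phosphate, MYC, interferon-stimulated and immediate early genes and B cell markers over both sets; and for pro-apoptotic members in the difference between sets. None of these lists passed camera in the comparison named.

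**Figure D2:**
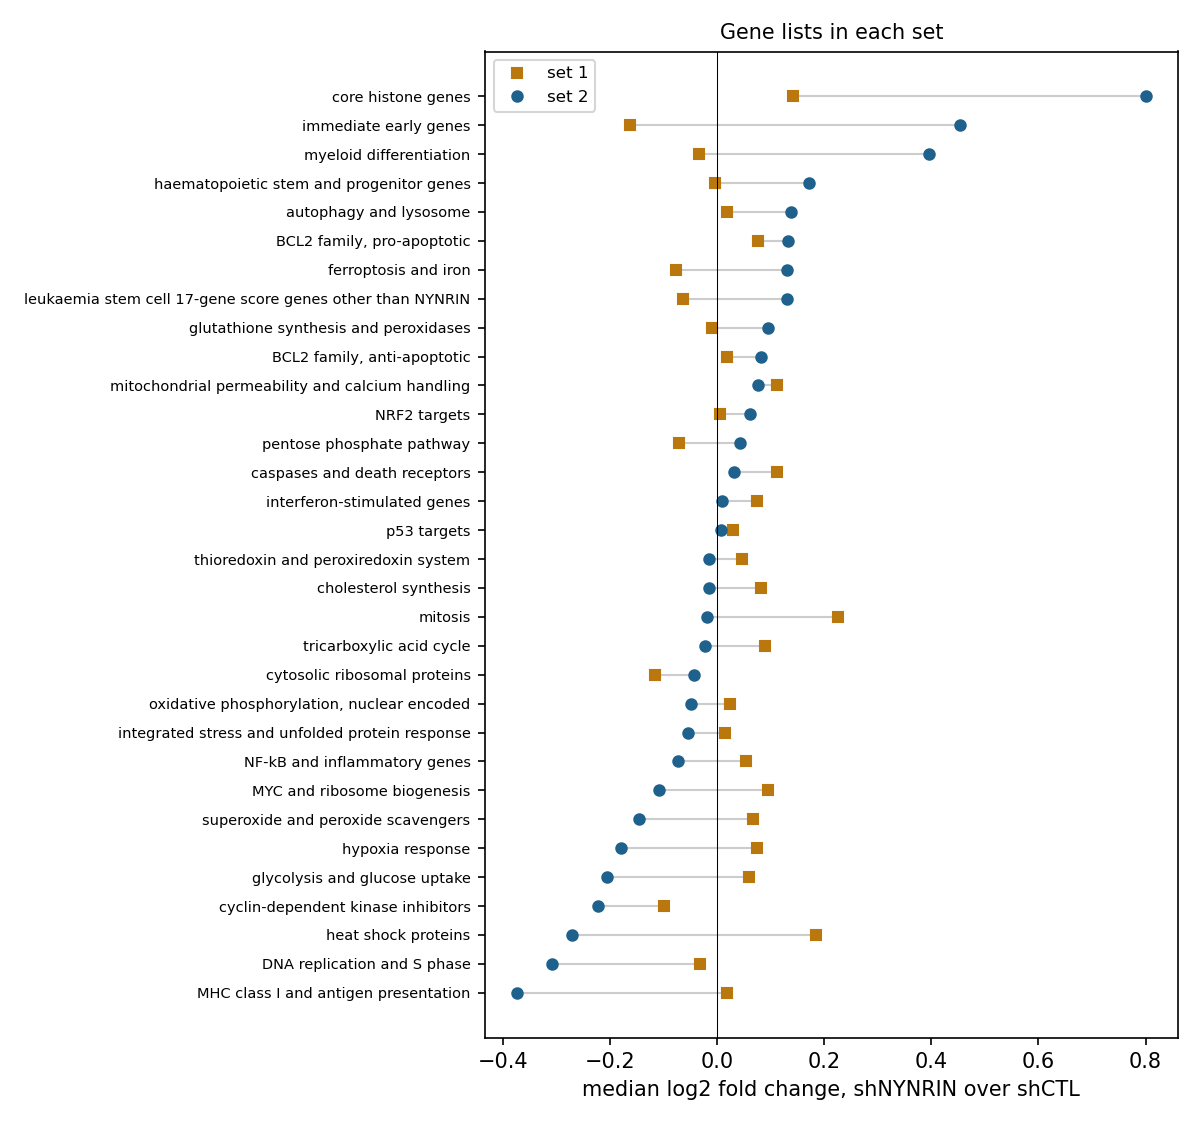
Median log2 fold change (shNYNRIN over shCTL) of the measured members of each of the 32 gene lists in set 1 (squares) and set 2 (circles). The immediate early genes have medians of -0.16 and 0.45 and the heat shock genes of 0.18 and -0.27 in sets 1 and 2.

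The sets were then compared directly. EGR1 fell in set 1 and rose in set 2, a difference of 1.20 between the log2 fold changes (limma adjusted p = 0.000207), and FOS and FOSB differed by 1.51 and 1.44. PSAT1 fell in set 1 and rose by 0.58 in set 2, a difference of 1.36. The effects on CHAC1 differed by 2.40 and those on MYB, a transcription factor of blood progenitors, by 0.66. The chaperones HSPH1 and HSP90AA1 rose by 0.60 and 0.27 in set 1 and fell by 0.54 and 0.52 in set 2, with differences of -1.14 and -0.79. The cell cycle inhibitor CDKN1A rose by 0.46 and fell by 0.45, a difference of -0.91.

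In total 2636 of 12939 genes differed in effect between the sets by limma, 1339 with a higher and 1297 with a lower log2 fold change in set 2. The 5 largest positive differences were in ENSG00000284651, CHAC1, HPGD, the spliceosomal RNA RNU4ATAC and SOD1P3, from 2.44 to 1.88, and the 5 largest negative in BCYRN1, SLC6A8, RNU6-30P, RNU6-882P and a Y RNA, Y_RNA|ENSG00000206739, from -2.48 to -1.70. ENSG00000284651, RNU4ATAC, BCYRN1, RNU6-30P and RNU6-882P are among the 990 genes of low mean count in set 1, so their differences are uncertain. The ENSG00000284651 difference was lost without shCTL replicate 1 or 2 or shNYNRIN replicate 4 (limma adjusted p up to 0.0732). Across genes, which are not independent replicates, the log2 fold changes of the sets had a Pearson r of -0.0248 and a Spearman rho of -0.0295. Of the 747 genes that passed in both sets 293 changed in the same direction and 454 in opposite directions, where independent lists of these sizes share 215 and 205 genes. The calls of both sets used the same residual variance of each gene, so an excess over 215 and 205 is partly built in. Of 18 immediate early genes 12 had a higher effect in set 2 and 1 had a lower one (12 and 1 adjusted over the list alone). For immediate early genes the camera adjusted p was 1.57e-08 (adjusted p = 0.125 with an estimated correlation). Of 11 heat shock genes 10 had a lower effect in set 2 (10 adjusted over the list alone). For heat shock genes the camera adjusted p was 7.04e-09 (adjusted p = 0.0952 with an estimated correlation). Of 27 mitosis genes 15 had a lower effect in set 2 (18 adjusted over the list alone). For mitosis genes the camera adjusted p was 3.76e-07 (adjusted p = 0.0952 with an estimated correlation). In the ferroptosis and iron list 6 had a higher effect in set 2 and 2 had a lower one (6 and 2 adjusted over the list alone). For the ferroptosis list the camera adjusted p was 0.0477 (adjusted p = 0.239 with an estimated correlation), a call lost without shNYNRIN replicate 1, 2 or 3 (camera adjusted p = 0.0685, 0.0869 and 0.0636, 0.0251 to 0.737 over 17 alternatives). Camera passed 17 of 32 lists for the difference, 0 with an estimated correlation (8 at an unadjusted p under 0.05), and fry 28. The count of genes was 1472 without shNYNRIN replicate 3, 1428 without shNYNRIN replicate 4 and 1723 without shCTL replicate 2.

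**Figure D3:**
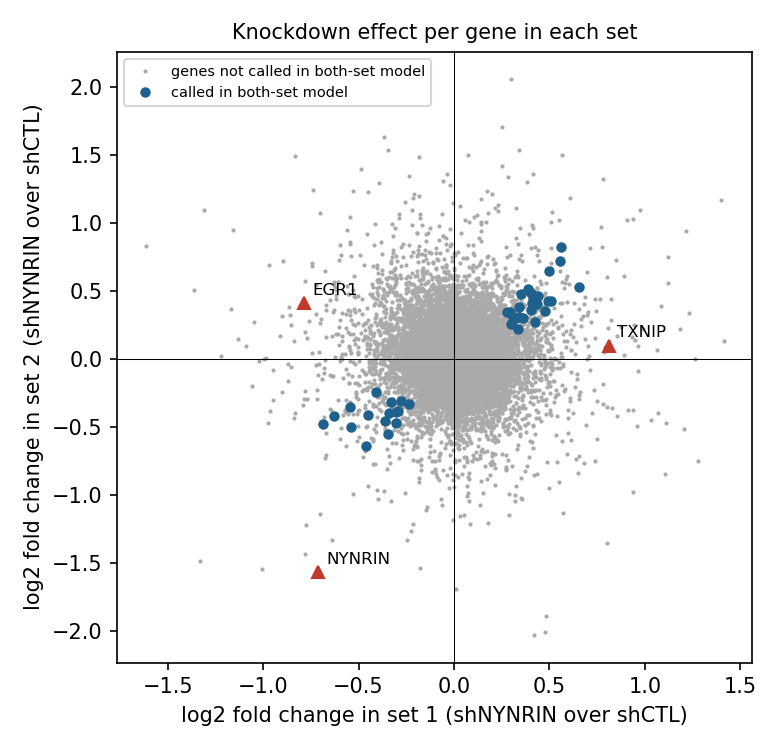
Log2 fold change of each of 12939 genes in set 1 (x axis) and set 2 (y axis), shNYNRIN over shCTL; blue points are the 41 genes that passed over both sets and triangles mark NYNRIN, TXNIP and EGR1. The cloud has a Pearson r of -0.0248 across genes, and EGR1 lies at -0.79 in set 1 and 0.41 in set 2.

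Marker genes of blood lineages were read as levels in the 8 libraries. The megakaryocytic integrin ITGA2B lay between 507 and 589 FPKM. The erythroid genes HBB, GYPB and KLF1 lay between 31.4 and 50.8, 45 and 60.6, and 52.96 and 72.3 FPKM. Other genes of the same lists were low, with highest values of 4.36 FPKM for HBA1, 4.01 for HBG1, 3.503 for PPBP and 2.46 for VWF, and of 0.0986 for SLC4A1 and 0.320 for AHSP in set 2. CD34, a progenitor marker, lay between 0.680 and 1.79 FPKM, and myeloperoxidase (MPO) was listed at 0 in the 4 libraries of set 2. Some other progenitor and myeloid genes were well above that, with GATA2 between 171 and 244, RUNX1 between 143 and 163, SPI1 between 62 and 82.0 and CD33 between 18 and 24.8 FPKM. The progenitor genes HOXA9, HLF and HMGA2 reached at most 0.24, 0.0365 and 0.0145 FPKM in set 2. Not every listed gene was found in set 2. All 14 listed erythroid, 6 of 8 megakaryocytic, 25 of 31 stem and progenitor and 27 of 31 myeloid differentiation genes were found. So were 13 of 17 T and NK cell, 7 of 11 B cell, 9 of 11 monocyte and macrophage and 10 of 12 stromal and packaging-line genes. Of the genes found, 12 of 14 erythroid and 6 of 6 megakaryocytic genes had a mean of at least 1 FPKM there. So did 21 of 25 stem and progenitor and 9 of 27 myeloid differentiation genes. The counts were 2 of 13 for T and NK cell, 3 of 7 for B cell, 1 of 9 for monocyte and macrophage and 1 of 10 for stromal and packaging-line genes. ALAS2, the first enzyme of haem synthesis in erythroid cells, rose over both sets (log2 fold change 0.43, limma adjusted p = 0.0479), a call lost without any of shCTL replicates 1 and 2 or shNYNRIN replicates 1, 2, 3 and 4 (limma adjusted p up to 0.175). Of 12 measured erythroid genes 1 rose (2 adjusted over the list alone) over both sets, 1 rose and 2 fell (2 and 2 adjusted over the list alone) in set 1 and 5 rose and 1 fell (5 and 1 adjusted over the list alone) in set 2 (camera adjusted p of 0.309 over both sets, 0.891 in set 1 and 0.1004 in set 2). By limma 0 of 6 megakaryocytic genes passed over both sets (2 lower adjusted over the list alone, 2 at an unadjusted p under 0.05), with VWF at -0.34 and ITGA2B at -0.11. That list passed camera towards lower values (camera adjusted p = 0.0424, adjusted p = 0.197 with an estimated correlation, 0.00710 to 0.383 over 27 alternatives), a call lost without shCTL replicate 1, shCTL replicate 4 or shNYNRIN replicate 2, 3 or 4 (camera adjusted p = 0.0632, 0.339, 0.0674, 0.0756 and 0.0571). Within the sets 1 fell (2 adjusted over the list alone) in set 1 and 1 fell (1 adjusted over the list alone) in set 2 (camera adjusted p of 0.331 and 0.101). The 3 measured B cell genes did not pass over both sets (camera adjusted p = 0.674), and the T and NK cell, monocyte and macrophage, and stromal markers had too few measured genes for a test. By fry the erythroid markers passed over both sets towards higher values (fry adjusted p = 0.0318). The megakaryocytic markers passed towards lower values (fry adjusted p = 0.00816), and the B cell markers did not pass (fry adjusted p = 0.950).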

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

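The interaction test and the test over both sets were planned. The tests of explanations, of other splits, of library-name numbers and of single samples far from the others were chosen, and the limits that decide them set, only after the result was seen.

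The knockdown effect differed between the sets for 2636 genes in the limma interaction test, among them NYNRIN (difference -0.85) and TXNIP (difference -0.71). A single response scaled by the depth of the knockdown and nothing else is argued against by a Pearson r of -0.0248 between the effects. That r cannot speak to a shared response beside handling by library-name number. Such handling would enter the effects of the sets with opposite signs and lower r. Group labels exchanged in set 2 are argued against by the NYNRIN log2 fold change of -1.57 there. An odd shCTL replicate 4 as the only cause is argued against by set 2 effects taken against shCTL replicate 3 instead. These had an r of -0.114 with set 1 effects over 5880 genes of at least 10 FPKM. Against shCTL replicate 4 the r was -0.107. Handling that followed the numbers of the library names (shCTL 3 and 4 beside shNYNRIN 1 and 2 in set 1, shCTL 1 and 2 beside shNYNRIN 3 and 4 in set 2) cannot be told apart from a real difference between sets: 2636 genes separated library-name numbers 1 and 2 from 3 and 4 and 1519 the tables, and in this design the first of these contrasts is the interaction itself. Paired by library-name number, TXNIP effects were 0.55 and 0.36, NYNRIN effects -0.48 and -1.80, and EGR1 effects -0.68 and 0.31. Over the 5880 genes, effects paired this way had an r of 0.0694. Each of them takes the control from a different table than the knockdown and so carries the difference between the tables. A biological difference between the sets, such as the hairpin used or the state of the cultures, stays open and was not tested.

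For the 41 genes over both sets chance was not excluded, since 2 of 34 splits of the 7 libraries into 3 and 4, the real one among them, gave as many genes. The other gave 305, several times the real count of 41, which points to a structure of the samples. It exchanges the groups within set 2 and so parts library-name numbers 1 and 2 from 3 and 4, the known difference between the sets, and no gene passed limma in any remaining split. Of the 7 splits that part every complete pair of library-name numbers, only the real one gave as many genes. The highest other gave 0 by limma. This cannot exclude chance either, since 1 of 7 is the smallest share possible. The restriction also leaves out the split with 305 genes, and the numbers are not shown to pair the libraries. The real contrast has a count of 0 with the library-name number as a block (limma, 2188 at an unadjusted p under 0.05). That block has no table term and its complete pairs span both tables, so a difference between the tables adds to its residual spread.

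Some erythroid and megakaryocytic genes, such as ITGA2B and KLF1, were high and CD34 low in every library labelled KG-1a, while other genes of these lists were low. Of 25 stem and progenitor genes found in set 2, 16 had a mean of at least 10 FPKM there, among them GFI1B and TAL1. Others were low. ERG and HOXA5 reached at most 1.61 and 2.09 FPKM, and HOXA9, HLF and HMGA2 at most 0.24, 0.0365 and 0.0145 FPKM in set 2. These levels alone do not tell a progenitor from an erythroid or megakaryocytic cell, so they do not speak for the label. A share of other cells that varied 3 times or more between libraries is argued against by ITGA2B, whose highest value was 1.16 times its lowest. Cells of another line or lineage than the label cannot be told apart from a change of the labelled line in culture, because no reference profile of the line was used here. The highest CD34 value was 1.79 FPKM, and GATA1, a transcription factor of these lineages, lay between 152 and 176 FPKM. No biological explanation was tested, as the design gives none.

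PCAT14 in the 4 shNYNRIN libraries had a sample far from the others, shNYNRIN replicate 2 at 20.8 FPKM, with a gap of 0.882 of the range; 1 of 44 groups stood out, where chance gives about 1 in 20. The second table lists 171 genes outside the first table with at least 1 FPKM in at least 2 of 3 libraries, the highest at 4.63 FPKM.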

How the results depend on the processing

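Tests with shCTL replicate 3, with genes of at least 10 FPKM alone, with the average over the sets and with the library-name numbers were chosen only after the result was seen, as was reading the effect of each set, and the other tests were planned. The planned size factors and count test were not run, as the tables hold no counts, and leaving out shCTL replicate 3 has no value because that library was not in the tests. Single-library depth, and with it the precision of low values, is not known here. The NYNRIN fall in set 1, in set 2 and in their difference passed limma in all 16, 16 and 15 alternatives, and the TXNIP rise in set 1 and its difference in all 18 and 17. Over both sets NYNRIN passed in 8 of 23 alternatives (limma adjusted p from 0.000303 to 0.423) and TXNIP in 6 of 27 (from 0.000189 to 0.445). TXNIP in set 2 passed in 2 of 18 (from 0.0399 to 0.295). The count over both sets was the least stable result.

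Over both sets, quantile normalization gave 8 genes (4 higher, 4 lower), and upper-quartile scaling 10 higher genes. A filter of 5 FPKM, which tests fewer genes, gave 89 genes (55 higher, 34 lower) and a NYNRIN log2 fold change of -1.05 that passed (limma adjusted p = 0.0420). Without a table term limma gave 0 genes (2065 at an unadjusted p under 0.05) and without a mean-variance trend 0 (2371 unadjusted), with 977 genes in set 1 and 1726 for the difference. Library weights gave 1025 genes (641 higher, 384 lower), NYNRIN at -0.77 (limma adjusted p = 0.0102) and TXNIP at 0.75 (0.00689). No gene passed limma with an absolute log2 fold change of at least 1 (0 genes) or at an adjusted p of 0.01 (0 genes), where 2423 had an unadjusted p under 0.05.

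The first table alone gave 1234 genes (704 higher, 530 lower), 7 lists, NYNRIN at -0.71 (limma adjusted p = 0.00458) and TXNIP at 0.81 (0.00246). The second table alone gave 3163 genes (1799 higher, 1364 lower), 16 lists, NYNRIN at -1.57 (limma adjusted p = 0.000799), and a mean of -0.013 for the mitosis list, below 0 where it was above 0 over both sets (camera adjusted p = 0.475, 1e-10 to 0.475 over 27 alternatives). The other reversed value was ENO1 in set 1, at 0.088 with quantile normalization (limma adjusted p = 0.0215, 0.0215 to 0.976 over 18 alternatives) against -0.026. Each table alone holds fewer samples than both together, and the cause of the other changes was not tested.

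With shCTL replicate 3 as deposited there were 356 genes (252 higher, 104 lower), 9 lists, NYNRIN at -1.13 (limma adjusted p = 0.0157), and TXNIP in set 2 at 0.088 (0.0474). With 0.5 added to it and genes of at least 10 FPKM there were 478 genes (292 higher, 186 lower), 4 lists in set 1, and TXNIP in set 2 at 0.085 (0.0399). Of the 41 genes 31 reach that level, and all 31 passed there. Genes of at least 10 FPKM alone gave 82 genes (43 higher, 39 lower) and 4 lists in set 1. The average over the sets gave 2304 genes (1388 higher, 916 lower), 12 lists, NYNRIN at -1.14 (limma adjusted p = 0.000303) and TXNIP at 0.46 (0.000469). Library-name numbers 1 and 2 against 3 and 4 in place of the table gave 527 genes (336 higher, 191 lower), 9 lists, NYNRIN at -1.27 (limma adjusted p = 0.0373) and TXNIP at 0.44 (0.0141).

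A replicate block by library-name number gave 0 genes by limma (2188 at an unadjusted p under 0.05), 6 lists, NYNRIN at -1.35 (limma adjusted p = 0.197) and TXNIP at 0.43 (0.183). It ended the calls of the genes named over both sets and left the list calls named there. It has no table term, so a difference between the tables adds to its residual spread. The same block with shCTL replicate 3 plus 0.5 and genes of at least 10 FPKM gave 145 genes (84 higher, 61 lower) and TXNIP at 0.45 (0.0281). The numbers in the titles did not pair the libraries, with r of -0.128, -0.174, -0.161 and -0.150 and each shCTL library closest to another number. A replicate block by title number gave 0 genes by limma (1305 unadjusted), 4 lists, NYNRIN at -1.0 (limma adjusted p = 0.423) and TXNIP at 0.57 (0.445), and 0 genes with shCTL replicate 3 plus 0.5 (1075 unadjusted).

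With an estimated correlation camera passed 0 lists over both sets, 0 in set 1, 0 in set 2 and 0 for the difference (1, 5, 9 and 8 at an unadjusted p under 0.05). Fry passed 0 over both sets (7 unadjusted), 17 in set 1, 21 in set 2 and 28 for the difference.

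With 1 library left out at a time, limma gave 0 to 2065 genes over both sets (0 to 1209 higher, 0 to 856 lower), 588 to 1466 in set 1, 1169 to 2965 in set 2 and 1428 to 2588 for the difference. The count of 2065 came without shCTL replicate 4, which leaves set 2 with no control. The count was 0 without shCTL replicates 1 and 2 (1865 and 1807 at an unadjusted p under 0.05) and without shNYNRIN replicates 1, 2, 3 and 4 (2002, 2080, 1886 and 1858). Set 1 had 588 and 617 genes without shCTL replicates 1 and 2 and 1232 and 1249 without shNYNRIN replicates 3 and 4. Set 2 had 1195 and 1169 without shNYNRIN replicates 3 and 4, and the difference 1472, 1428 and, without shCTL replicate 2, 1723. Lists passed by camera ranged from 4 to 8 over both sets (7 without shNYNRIN replicate 1 and 8 without shCTL replicate 4), 6 to 9 in set 1 and 14 to 19 for the difference. NYNRIN over both sets lay between -1.15 and -0.71. Without shCTL replicate 4 NYNRIN was at -0.71 (limma adjusted p = 0.00116) and TXNIP at 0.81 (0.000189). Over the genes and lists chosen for the text, 13593 comparisons with an alternative kept direction and side of the threshold, 1186 kept the direction and lost the call, 509 gained one, 2 turned, and 26 counts in 1 direction moved by over 1.5 times.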

Other observations

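The genes in this part were picked after their values were seen, from the planned test over both sets. CIRBP, a cold-inducible RNA-binding protein like RBM3, fell from 56.2 ± 3.40 to 44.5 ± 1.06 FPKM in set 1 and from 52.1 to 41.7 ± 0.234 FPKM in set 2 (SD, n = 2 where given), a log2 fold change of -0.32 over both sets. Tropomyosin 4 (TPM4), which binds actin filaments, rose by 0.31 on the log2 scale, the intermediate filament vimentin (VIM) by 0.28, the tubulin TUBA1A by 0.40, the GTPase RHOC by 0.33 and WIPF2, a partner of the actin regulator WASP, by 0.39. HELLS, a chromatin remodeller that DNA methylation needs, fell by 0.33 and the chromatin reader PSIP1 by 0.27. These genes are 8 of the 41 that passed over both sets in limma, and no list of their kind was fixed, so no group is tested here. Each call was lost without any of shCTL replicates 1 and 2 or shNYNRIN replicates 1, 2, 3 and 4, with a limma adjusted p between 0.000744 and 0.423 over 27 alternatives. The tubulin gene TUBAL3, also among the 41 and named earlier, went the other way, with a log2 fold change of -0.53. The rises above therefore do not cover every cytoskeletal gene that passed.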
